A study of Mus musculus with 12 samples.

How the data were processed

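Total RNA from QF and TA muscle of Dysf_null (C57BL/10-SJL.Dysf) and Control (C57BL/10) mice aged 3 weeks had been hybridised to 12 single-channel arrays, 3 for each of the 4 combinations of genotype and muscle. The groups and the replicate numbers were taken from the labels. The deposited values were intensities on a linear scale, 1 per probe set and array. On each array their mean without the lowest and highest 2% lay between 200.1 and 200.2, so the authors had scaled each array to a common mean, as the values show. The software, background correction and summarisation used by the authors are not given in the sources used here.

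The table held 12488 probe sets, of which 66 were controls and were left out. The medians of the deposited intensities differed 1.47-fold between arrays, above the limit of 1.25-fold set before the data were examined, so the 12422 remaining probe sets were quantile normalized. A floor was set at the 25th percentile of all values (intensity 23.025, log2 4.53), which also took in 4 values of 0, and log2 was taken. The 10331 probe sets above the floor on at least 3 arrays were tested. A difference whose lower group had all its arrays at the floor is a bound and is given as "at least". No depth applies to arrays, and the number of arrays limits the precision: the median SE of a difference between 2 groups was 0.323 on the log2 scale.

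Probe sets were named from a table of the platform's annotation. Of the 12422, 10833 had 1 gene symbol, 396 had several and 1193 were not in that table, and those with several or none were not named. The symbols were looked up by gene number in a reference gene table (GRCm38.p6), which changed 0 of them. That table was also used to match the names in the gene lists and for gene order and chromosomes. The kept probe sets with 1 symbol covered 7310 genes, 1540 of them by more than 1 probe set, and each probe set was tested on its own. Among the genes called, another probe set pointed the opposite way for 3 genes in the QF comparison, 4 in TA, 5 between muscles in controls, 1 in Dysf_null mice, 1 for the interaction and 5 for the average. No kept or removed probe set carried the name Dysf. The allele of the SJL strain is known to remove part of the transcript in frame, so a probe set outside that part would not have checked the genotype.

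Group means were fitted with limma 3.58.1 in R 4.3.3 to all 12 arrays, with 8 residual degrees of freedom, moderated variances with an intensity trend, and two-sided tests. Benjamini-Hochberg adjustment ran over the 10331 probe sets, and an adjusted p under 0.05 was called. The 6 comparisons were Dysf_null minus Control in QF and in TA, their average, TA minus QF in Control and in Dysf_null mice, and the interaction (genotype difference in TA minus that in QF). Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

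Gene lists were fixed before the data were examined: 28 lists of programmes and cell type markers with 707 genes, of which 570 were on the array and 529 were measured. They covered slow and fast fibre contractile genes, limb patterning, embryonic muscle, membrane repair, sarcolemma, complement, extracellular matrix, oxidative phosphorylation, fatty acid use, glycolysis, protein turnover, heat shock, immediate early, clock, cell cycle, ribosomal protein and antigen presentation genes. Markers covered macrophages, lymphocytes, granulocytes, fat, endothelial and mural cells, fibroblasts and tendon, blood, nerve, and bone, cartilage and skin. The 27 lists with at least 5 measured genes were tested with limma's camera at its preset correlation of 0.01, on the probe set of each gene with the highest mean, with adjustment over the lists of a comparison. The sex-linked list had 3 measured genes and was not tested. With an estimated correlation in place of the preset one, 8 of 13 list calls held in QF, 13 of 15 in TA, 12 of 15 for the average, 2 of 7 in Control, 2 of 5 in Dysf_null and 5 of 8 for the interaction. List p-values in the text are at the preset correlation unless stated otherwise, and their size depends on it. For extracellular matrix genes in QF the camera adjusted p was 9.69e-18 at the preset correlation and 0.00026 with the estimated one.

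The genes named in the text were chosen by a rule set before the data were examined. It took up to 12 genes each way per comparison with the largest differences among those called, whose groups did not overlap in any array, and up to 4 members of each list with the smallest p-values. For the interaction it took up to 10 each way with no rule on overlap. Genes outside it are said to have been named after their values were seen, which also holds for Csrp3 and Ankrd2 in the comparison of muscles in Dysf_null mice. Calls near Dysf were compared with calls elsewhere by Fisher's exact test, over the 100 measured genes on each side in the reference gene order.

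Arrays of the same replicate number were compared by the correlation of their deviations from their group means. Between genotypes within a muscle, all 3 same-numbered pairs exceeded 0.1 (0.390, 0.711 and 0.660 in QF, 0.182, 0.114 and 0.231 in TA). Across muscles they did not (-0.0122, -0.0931 and -0.00575 in Control, 0.0774, -0.141 and 0.123 in Dysf_null). Differently numbered arrays across muscles reached 0.268 (Dysf_null_TA 2 with Dysf_null_QF 3). The TA values were not beyond that, so the pairing was clear in QF only. The numbers come from the labels, which do not say what they mark. The fit with the replicate number as a block within each muscle is therefore given beside each count of probe sets it moved and for the lists where it is named. That fit shares the same variance per probe set between both muscles. Calls it added in TA can thus come from the deviations it removed in QF, and are no evidence of a pairing in TA.

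The alternatives were the values as deposited, a floor at the 10th percentile, a log transform with an added constant, no filter and a filter at the median of all values (82.0), no intensity trend, only the groups of a comparison, the replicate number as a block, and each array left out in turn. After seeing the data, the block within each muscle, array weights and leaving out both QF arrays numbered 2 were added. The procedure was tested on simulated data made from the 10331 probe sets with 200 changed, in 5 simulations of the QF comparison. Of changes of 2-fold 30.6% were called and of changes of 4-fold 77.6%, 4.59% of the calls were unchanged probe sets, and 0 had the wrong sign. The camera test called a list shifted by 0.5 (log2) in 10 of 10 simulations of the TA comparison, and smaller shifts were not simulated. The simulated noise was independent between genes and between arrays, and changed probe sets had means clearly above the floor. Deviations shared between arrays, as seen in QF, were not simulated, so these shares need not hold for the real data.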

Results

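Gene expression was measured on 12 arrays of total RNA from skeletal muscle of mice aged 3 weeks. Mice of the line C57BL/10-SJL.Dysf, which carries the mutant dysferlin gene of the SJL strain on the C57BL/10 background and is labelled as lacking dysferlin, were compared with C57BL/10 controls. Dysferlin is a membrane protein of the muscle fibre that takes part in the repair of the sarcolemma. From each genotype 2 muscles were taken, called QF and TA in the labels, which from knowledge of the study are the proximal quadriceps femoris and the distal tibialis anterior. The 4 groups (Dysf_null_QF, Control_QF, Dysf_null_TA and Control_TA) held 3 arrays each. The title of the series gives the question, whether the lack of dysferlin changes the difference between a proximal and a distal muscle. Nothing states that the 3 replicates of a group came from separate mice, so the p-values measure the spread between these arrays, which may be partly technical.

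No probe set was named for Dysf, so the transcript of the targeted gene was not analysed here, and the genotype labels were not checked against it. The muscle labels could be set against Hoxa11, a homeobox gene that patterns the lower limb segment: all 6 QF arrays were at the floor (log2 4.53), and the 6 TA arrays lay at 6.18 or above. The 2 QF arrays numbered 2, 1 of each genotype, stood apart from the rest, with median correlations with the other arrays of 0.876 (Dysf_null) and 0.866 (Control), against 0.926 to 0.959 for the other 10. Their deposited median intensities were 107.1 and 106.1, against 72.8 to 84.3 on the other arrays. Differences below are on the log2 scale, for 3 arrays against 3, with the standard error (SE) of the limma fit. Adjusted p-values are limma's with Benjamini-Hochberg adjustment. All 4 groups share the same variance per probe set, so a probe set has the same SE in QF and in TA. Where its spread differs between the muscles, that SE is too small for the muscle with the wider spread and too large for the other. An entry marked "at least" had every array of the lower group at the floor.

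In QF, transcripts of the connective tissue and of antigen presentation were higher in Dysf_null than in Control mice, and those of the metallothioneins Mt1 and Mt2 were lower. Col3a1, a fibrillar collagen, rose by 1.92 ± 0.20 (adjusted p = 0.0019), Sparc, a matrix glycoprotein, by 0.96 ± 0.13 (0.00654), and Cd74, the invariant chain of class II molecules, by 1.14 ± 0.17 (0.00961). The metal-binding protein Mt2 fell by 1.82 ± 0.22 (0.00439), and the methyltransferase Inmt fell by 3.20 ± 0.39 (0.00439). In all, 47 of 10331 probe sets passed, 31 higher and 16 lower.

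Extracellular matrix genes moved together in QF. Of 29 measured, 3 rose, 0 fell and 26 did not pass (13 rose adjusted over the list alone). A positive difference was seen for 27, and the list was shifted upward (median 0.52, camera adjusted p = 9.69e-18, and 0.00026 with an estimated correlation). The 3 were Sparc, Col6a3 (0.81 ± 0.15) and Postn, a matrix protein of healing tissue, which was 2.83-fold higher. Col3a1 was called on 1 of its 3 probe sets, and the other 2 gave 0.57 and 0.67. Markers of fibroblasts and tendon were shifted the same way (median 0.33, adjusted p = 2.01e-05), with 2 of 14 risen, the small proteoglycans Fmod (1.51 ± 0.26) and Kera (1.41 ± 0.27), and 4 adjusted over the list alone. Sfrp4 (2.33 ± 0.40) and C1qtnf3 (1.82 ± 0.32), both secreted proteins, rose as well.

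Of 25 antigen presentation and interferon genes, 4 rose in QF and 21 did not pass (10 rose adjusted over the list alone). The list median was 0.35 (camera adjusted p = 9.46e-10, and 0.0062 with an estimated correlation). Beside Cd74, H2-Aa rose by 2.59 ± 0.47, B2m by 0.88 ± 0.16 and H2-K1 by 0.74 ± 0.12, 1 of whose other probe sets had a difference of -0.20. For H2-Aa, arrays Control_QF 1 and Control_QF 2 were at the floor, which limits the size of its difference. Macrophage and monocyte markers were shifted upward with them (median 0.28, adjusted p = 0.00135), although 0 of the 25 passed over all probe sets and 1 rose adjusted over the list alone (3 with the replicate numbers as a block within each muscle). The lysozyme gene Lyz2 had a difference of 0.82 ± 0.19 (adjusted p = 0.0968, and 0.0136 with that block). Lymphocyte markers were not shifted (adjusted p = 0.356), with Thy1 alone risen (1.19 ± 0.23) among 11, also by the list alone.

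Genes of protein turnover and atrophy were lower in QF of Dysf_null mice. Of 25, 3 fell and 22 did not pass (7 fell adjusted over the list alone). The list median was -0.35 (camera adjusted p = 2.02e-12, and 0.0062 with an estimated correlation). The 3 were Mt2, Mt1 (-1.56 ± 0.28) and the lysosomal protease Ctsl (-0.79 ± 0.12), while the proteasome subunit Psmd4 gave -0.64 ± 0.18 (adjusted p = 0.204, and 0.0183 with that block). Further genes that fell were the cell cycle inhibitor Cdkn1a (-1.90 ± 0.36 on 1 of 2 probe sets), glutamine synthetase Glul (-1.43 ± 0.24), the mitophagy receptor Bnip3 (-1.24 ± 0.18), the reticulophagy regulator Retreg1 (-1.49 ± 0.16), the translation repressor Eif4ebp1 (-1.04 ± 0.17) and Fkbp5 (-1.20 ± 0.22), a glucocorticoid-responsive co-chaperone. Cell cycle genes were shifted upward (median 0.40 over 30 genes, adjusted p = 3.22e-05) with none past the threshold alone and Stmn1 risen adjusted over the list alone (1.29 ± 0.26), and also with that block (adjusted p = 0.00817).

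Membrane repair genes were shifted upward in QF (median 0.15, adjusted p = 0.00172). Of 18, the annexin Anxa5 rose (0.92 ± 0.12, adjusted p = 0.00464) and 17 did not pass (3 rose adjusted over the list alone). Anxa1 rose by 1.24 ± 0.23 on 1 of 3 probe sets. Of 9 blood and erythroid markers, Bpgm rose (0.72 ± 0.14) and 8 did not pass (3 adjusted over the list alone; median 0.23, adjusted p = 0.00172). The uncoupling protein of brown fat, Ucp1, rose by 1.63 ± 0.27, while the 19 fat cell markers were not shifted (adjusted p = 0.696; 1 rose, and adjusted over the list alone, or with that block, 1 rose and 2 fell). Immediate early genes (adjusted p = 0.0196), complement genes (0.0403) and endothelial markers (0.0403) were shifted upward, and oxidative phosphorylation (0.0403) and fatty acid use (0.0466) downward, with none of their genes past the threshold and, adjusted over the list alone, only 1 immediate early gene risen. With that block 2 immediate early genes and 1 complement gene rose and 1 fatty acid gene fell. With an estimated correlation these 5 lists gave adjusted p = 0.0509, 0.0900, 0.0900, 0.0673 and 0.185.

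Of 33 named calls in QF, 11 held without any single array, namely Anxa5, Bnip3, Cd74, Col3a1, Ctsl, Inmt, Mt2, Postn, Retreg1, Sparc and Tmsb10 (1.38 ± 0.19). The count of 47 was 16 without both QF arrays numbered 2, 23 with array weights, 7 without the intensity trend in the variance and 273 with the replicate numbers as a block within each muscle. That block also raised the number of extracellular matrix genes past the threshold to 13 of 29, of antigen presentation genes to 9 of 25, of protein turnover genes to 6 of 25, of membrane repair and of fibroblast and tendon genes to 4 each and of blood genes to 3 of 9. With the QF arrays fitted alone limma called 0, with 406 at an unadjusted p under 0.05, limma without the trend called 0 (359), a gene by gene test without moderation 0 (439) and limma with the replicate numbers 8 (1183). Leaving out 1 array gave 26, 27 and 21 without Dysf_null_QF 1, Control_QF 2 and Dysf_null_QF 3, 22 and 82 without Control_QF 1 and 3, 30 and 28 without Dysf_null_TA 2 and 3, and 29 without Control_TA 2.

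In TA, Dysf_null mice had lower levels than controls of Csrp3 and Ankrd2, which encode proteins of the Z-disc and the sarcomere, and higher levels of transcripts of granulocytes, red cells and antigen presentation. Csrp3, the muscle LIM protein, fell by 2.68 ± 0.24 (adjusted p = 0.00023), and Ankrd2, a titin-binding ankyrin repeat protein, fell by 2.30 ± 0.16 (1.42e-05). S100a9, a calcium-binding protein abundant in neutrophils, rose by 2.74 ± 0.33 (0.00179), and Alas2, which starts haem synthesis in red cells, by 2.00 ± 0.23 (0.00179). In all, 42 of 10331 probe sets passed, 26 higher and 16 lower.

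Of 18 slow and oxidative fibre contractile genes, 3 fell in TA and 15 did not pass (also 3 adjusted over the list alone; median -0.16, adjusted p = 7.33e-06). These were Csrp3, Ankrd2 and Fhl1 (-0.65 ± 0.11), which are regulators at the Z-disc and the sarcomere, and the slow myosin light chain gene Myl2 gave 0.33 ± 0.12 (adjusted p = 0.655). Ankrd1, the cardiac relative of Ankrd2, fell by 2.25 ± 0.34, the actin-binding protein Xirp1 by 1.29 ± 0.16, and the small heat shock protein Cryab by 1.41 ± 0.14 on 1 of 2 probe sets, the other giving 0.06. Cryab was also the gene that fell among 21 sarcolemma and sarcomere integrity genes (median -0.13, adjusted p = 0.00514; 1 adjusted over the list alone). Among 23 heat shock genes 2 fell, Cryab and Hspb8 (-0.70 ± 0.13), and 3 did adjusted over the list alone (adjusted p = 0.0132, and adjusted p = 0.0721 with an estimated correlation). Among 23 glycolysis and glycogen genes 2 fell, hexokinase Hk2 (-1.01 ± 0.16) and the glycogen branching enzyme Gbe1 (-1.28 ± 0.22), and 3 adjusted over the list alone (adjusted p = 0.0132).

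Granulocyte and mast cell markers were shifted upward in TA (median 0.69, adjusted p = 7.49e-08). Of 15, S100a9 and S100a8 (2.32 ± 0.38) rose and 13 did not pass, with 4 risen adjusted over the list alone; the granule genes Ngp and Camp gave 2.02 ± 0.47 and 1.48 ± 0.37 (adjusted p = 0.152 and 0.22, and 0.0454 and 0.0176 with the replicate numbers as a block within each muscle). Of 9 blood and erythroid markers, 4 rose (5 adjusted over the list alone; median 0.82, adjusted p = 5.31e-13): Alas2, Bpgm (1.15 ± 0.14), Hba-a1 (0.82 ± 0.14) and Car2 (1.12 ± 0.21). The matrix proteases Mmp9 (at least 3.12 ± 0.53) and Mmp13 (2.23 ± 0.40) and the osteoclast phosphatase Acp5 (1.87 ± 0.25) rose. The bone sialoprotein gene Ibsp rose by 2.68 ± 0.45 on 1 probe set and gave -0.35 on the other, and the 13 bone, cartilage and skin markers were not shifted (adjusted p = 0.506).

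Antigen presentation and interferon genes were shifted upward in TA as in QF (5 of 25 rose, 7 adjusted over the list alone; median 0.31, adjusted p = 9.61e-10), with Cd74 at 1.26 ± 0.17, H2-Aa at 2.54 ± 0.47, H2-D1 at 0.93 ± 0.15, B2m at 0.92 ± 0.16 and H2-K1 at 0.86 ± 0.12, 1 of whose other probe sets gave -0.36. Macrophage markers were shifted upward (median 0.28, adjusted p = 0.00291), but the 1 of 25 that passed, also by the list alone, was Cd68, which fell by 1.27 ± 0.19. Lymphocyte markers had an adjusted p of 0.0381 with none of 11 past the threshold, adjusted p = 0.30 with an estimated correlation and adjusted p = 0.0599 with the replicate numbers as a block within each muscle, which had 1 gene risen. Of 23 immediate early genes, Fos rose (2.11 ± 0.34) and 22 did not pass (2 rose adjusted over the list alone; median 0.25, adjusted p = 4.74e-05).

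Extracellular matrix genes were shifted upward in TA (median 0.31, adjusted p = 2.94e-09) with none of 29 past the threshold (5 with the replicate numbers as a block within each muscle) and 3 risen adjusted over the list alone, and fibroblast and tendon markers with them (median 0.30, adjusted p = 5.89e-05; Fmod rose by 1.51 ± 0.26 among 14, 3 adjusted over the list alone). Cell cycle genes were shifted upward (median 0.28, adjusted p = 0.000828), and protein turnover genes (median -0.20, adjusted p = 6.15e-06) and oxidative phosphorylation genes (median -0.09, adjusted p = 0.00514) downward, with none of their genes past the threshold and, adjusted over the list alone, only 1 protein turnover gene fallen (2 with that block). The poly(A) polymerase gene Tent5c rose by 1.96 ± 0.20, and the exonuclease gene Isg20 by at least 2.60 ± 0.32.

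Of 34 named calls in TA, 13 held without any single array, among them S100a9, Alas2, Bpgm, Acp5, Tent5c, Isg20, Cd74, H2-K1, Csrp3, Ankrd2, Cryab and Xirp1. The count of 42 was 159 with the replicate numbers as a block within each muscle, 192 with array weights and 51 with the TA arrays fitted alone. That block also raised the number of granulocyte markers past the threshold to 4 of 15, of immediate early genes to 4 of 23, of blood markers to 5 of 9, of heat shock and of glycolysis genes to 3 each and of sarcolemma and of fibroblast and tendon genes to 2 each, and 2 macrophage markers rose. It was 25, 17 and 14 without Dysf_null_TA 1, 2 and 3, and 23, 19 and 19 without Control_TA 1, 2 and 3.

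**Figure D1:**
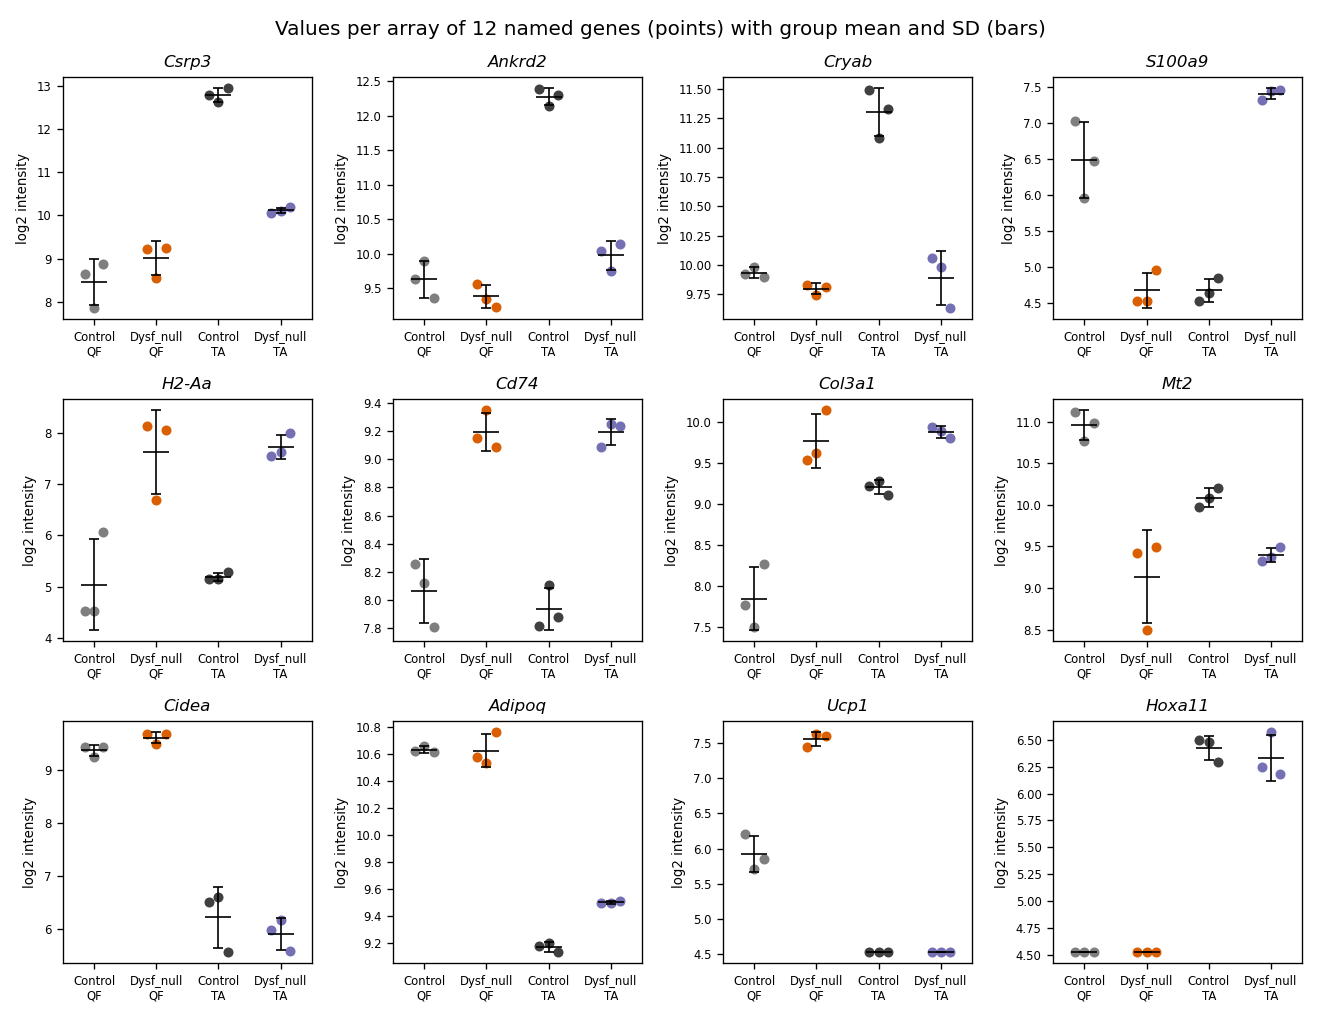
Log2 intensity of 12 named genes on each array (vertical axes, 1 panel per gene, not starting at 0), with points for the 3 arrays of each group and bars for the group mean and SD. Csrp3, Ankrd2 and Cryab were higher on every Control_TA array than on any other array, with Csrp3 in Dysf_null_TA between Control_TA and QF. S100a9 was high in Control_QF and Dysf_null_TA. H2-Aa and Cd74 were higher in Dysf_null mice in both muscles, and the fat cell genes Cidea, Adipoq and Ucp1 were higher in QF.

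Averaged over both muscles, 113 probe sets differed by genotype, 81 higher and 32 lower in Dysf_null mice. Genes that rose and kept the call without any single array included H2-Aa (2.56 ± 0.33, adjusted p = 0.0018), Fos (1.84 ± 0.24, 0.00186) and Tent5c (1.61 ± 0.14, 0.000201), and genes that fell and kept it included Ankrd1 (-1.61 ± 0.24, 0.005), Mt2 (-1.26 ± 0.15, 0.00127) and Mt1 (-1.14 ± 0.20, 0.0128). The size for H2-Aa is limited by the floor, at which Control_QF 1 and Control_QF 2 lay. Of the antigen presentation list 7 of 25 rose, and of the extracellular matrix list 6 of 29, or 10 and 18 adjusted over the list alone. Of the blood and erythroid list 4 of 9 rose (5 adjusted over the list alone), Alas2 by 1.48 ± 0.17. Of the protein turnover list 3 of 25 fell (12 adjusted over the list alone), and the lipid droplet gene Plin4 (-0.80 ± 0.15) and the lipase gene Pnpla2 (-0.54 ± 0.10) fell among the 19 fat cell markers, which were not shifted as a list (adjusted p = 0.271; 2 rose and 2 fell adjusted over the list alone). The calls of Plin4 and Pnpla2 were lost when 1 of 5 and 1 of 6 arrays was left out (adjusted p up to 0.0703 and 0.0791). The count was 474 with the replicate numbers as a block within each muscle, where 19 matrix, 9 antigen presentation, 5 blood and 2 fat cell genes rose and 11 protein turnover and 2 fat cell genes fell. The count was 56 without the intensity trend and 191 with array weights. It was 64 and 60 without Dysf_null_TA 2 and 3, and 72, 63 and 67 without Control_TA 1, 2 and 3.

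The genotype differences of both muscles were positively correlated across probe sets (Pearson r = 0.193, Spearman rho = 0.161), and probe sets are not independent replicates. The r was 0.158, 0.112 and 0.124 without Dysf_null_QF 2, Control_QF 3 and Dysf_null_TA 2, and 0.252 with the stricter filter on low values. There were 9 probe sets called higher in both muscles, against 0.078 for independent lists: Cd74, H2-Aa, B2m, H2-K1, Tent5c, Serpinf1, Bpgm, Tpm4 and Fmod. The lists were not independent, since both comparisons used the same variance estimate per probe set. Nothing states that QF and TA came from different mice either, so the excess over 0.078 is no measure of replication. Serpinf1 and Tpm4 were named after their values were seen, and a further probe set of Serpinf1 gave -0.17 in QF. For calls lower in both the count was 0, against 0.0248, and S100a9 fell in QF (-1.82 ± 0.33) and rose in TA. For S100a9, 2 of the 3 Dysf_null_QF arrays and 1 of the 3 Control_TA arrays were at the floor and the others were near it, so the floor limits the size of its differences, the interaction included. A segment of SJL sequence linked to Dysf would differ together with the genotype, so calls near Dysf were counted. The share of genes called there was not shown to differ from that elsewhere. Of the 200 measured genes nearest to Dysf in the reference gene order, 4 (2%) were called in the average, against 94 of 7102 others (1.32%), an odds ratio of 1.52 with a 95% interval from 0.402 to 4.09 (two-sided Fisher's exact test, p = 0.346). The 4 were Fkbp9, Hk2, Inmt and Tmsb10, listed here after their values were seen. The test counted genes and did not weigh the size of their differences. For these 4, which include Inmt and Tmsb10 named in QF and Hk2 named in TA, an effect of a linked segment cannot be told apart from the lack of dysferlin. All 200 genes were taken from the chromosome of Dysf, which had 423 measured genes. A smaller linked segment could be diluted in them, so the test cannot exclude one. With 50 genes on each side 2 of 100 were called (odds ratio 1.51, 95% interval from 0.178 to 5.75).

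Between the muscles of control mice, Csrp3, Ankrd2 and Fhl1 were higher in TA and genes of fat cells were higher in QF. Csrp3 was higher in TA by 4.35 ± 0.24 (adjusted p = 1.69e-06), Ankrd2 by 2.65 ± 0.16 (1.69e-06), Fhl1 by 1.73 ± 0.11 (3.18e-06) and Hoxa11 by at least 1.90 ± 0.25 (0.00232). The adipokine gene Adipoq (TA minus QF, -1.46 ± 0.11, adjusted p = 1.15e-05) and the lipid droplet gene Cidea (-3.14 ± 0.27, 4.62e-05) were lower in TA. In all 76 probe sets passed, 42 higher and 34 lower in TA.

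Of 19 fat cell markers, 8 were lower in control TA, 0 were higher and 11 did not pass; adjusted over the list alone 15 were lower. All 19 had a negative difference, with a median of -1.07 (adjusted p = 7.52e-26). They included Pck1 (-2.23 ± 0.27), Cidec (-2.20 ± 0.36) and Thrsp (-1.28 ± 0.17). Outside the list, the carboxylesterase Ces1d (-3.10 ± 0.42), the cysteine dioxygenase Cdo1 (-2.55 ± 0.15) and Adig (-1.82 ± 0.21), all expressed in fat tissue, were lower too. Of 18 slow and oxidative contractile genes 4 were higher and 1 lower in control TA (5 and 5 adjusted over the list alone), and the list as a whole was not shifted (adjusted p = 0.203). Myoglobin, Mb, was higher by 0.99 ± 0.14 on 1 of 2 probe sets, the other giving -0.32. Within the list, 9 slow contractile isoforms grouped after their values were seen, and leaving out Csrp3, Ankrd2, Fhl1 and Mb, had lower values in TA in 8 of 9 cases, with a median difference of -0.48.

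Extracellular matrix genes were shifted toward TA in control mice (median 0.38, adjusted p = 2.98e-05), with none of 29 past the threshold and, adjusted over the list alone, 4 higher and 1 lower. Cryab was higher in TA (1.37 ± 0.14), 1 of 23 heat shock genes (3 adjusted over the list alone; adjusted p = 0.00063, and adjusted p = 0.0628 with an estimated correlation). Ctsl (-1.19 ± 0.12) and the growth inhibitor Mstn (-1.01 ± 0.21) were lower among 25 protein turnover genes (3 adjusted over the list alone; adjusted p = 2.98e-05, and adjusted p = 0.0663 with an estimated correlation). Glycolysis genes (2 of 23 higher, 6 adjusted over the list alone), oxidative phosphorylation genes (Sdhd higher, 0.64 ± 0.09, 1 of 34) and membrane repair genes (0 of 18, 1 adjusted over the list alone) had adjusted p = 0.0193, 0.037 and 0.037, and with an estimated correlation adjusted p = 0.0663, 0.0782 and 0.11. Of 32 named calls 21 held without any single array. Among those given here, Cidec was lost when 1 of 3 arrays was left out (adjusted p up to 0.0789) and Mstn when 1 of 8 was (0.21). The count of 76 was 42 without the intensity trend and 21 with these 2 groups fitted alone. It was 46 and 145 without Control_QF 1 and 3, and 37, 38 and 38 without Control_TA 1, 2 and 3.

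In Dysf_null mice, fat cell genes were again lower in TA than in QF, while Csrp3 (1.11 ± 0.24, adjusted p = 0.123) and Ankrd2 (0.59 ± 0.16, 0.361) did not pass. Cidea (-3.70 ± 0.27, adjusted p = 5.22e-05), Pck1 (-2.38 ± 0.27, 0.00091) and Adipoq (-1.12 ± 0.11, 0.000254) were lower in TA, and Ucp1 differed by -3.03 ± 0.27, a bound since all TA arrays were at the floor. Of 19 fat cell markers 6 were lower and 13 did not pass (15 lower adjusted over the list alone; median -0.86, adjusted p = 2.06e-31). Hoxa11 was higher in TA by at least 1.80 ± 0.25 and the zinc finger gene Zic1 by at least 1.48 ± 0.23. S100a9 (2.74 ± 0.33) and S100a8 (2.08 ± 0.38) were higher in TA, 2 of 15 granulocyte markers (4 adjusted over the list alone; median 0.80, adjusted p = 9.05e-05).

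Of 18 slow and oxidative contractile genes in Dysf_null mice, Fhl1 (0.86 ± 0.11) and Mb (0.74 ± 0.14, with -1.17 on its other probe set) were higher in TA and Myl2 (-0.72 ± 0.12) lower (4 higher and 6 lower adjusted over the list alone; adjusted p = 0.407). The 9 slow contractile isoforms were lower in 8 of 9 cases, with a median difference of -0.62. Oxidative phosphorylation, glycolysis and blood lists had adjusted p = 0.0312, 0.0195 and 0.033, and adjusted p = 0.0772, 0.0772 and 0.116 with an estimated correlation; 1, 0 and 0 of their genes passed, and 1, 4 and 2 adjusted over the list alone. In all 31 probe sets passed, 10 higher and 21 lower in TA. Of 22 named calls 11 held without any single array. Among those given here, Zic1 and Myl2 were lost when 1 of 5 arrays was left out (adjusted p up to 0.0833 and 0.101), S100a8 when 1 of 10 was (0.246) and Mb when 1 of 11 was (0.271). The count was 52 with array weights and 9 with these 2 groups fitted alone, and 20 without Dysf_null_TA 2.

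The muscle differences of both genotypes correlated across probe sets with r = 0.473 (rho = 0.450), but with r = 0.214 without both QF arrays numbered 2 (0.186 without that of Dysf_null alone and 0.227 without that of Control alone). Of 19 probe sets called in both genotypes, 6 were higher in TA in both, 12 lower in both and 1, S100a9, opposite. Same-numbered QF arrays of both genotypes deviated together, so these counts and r include shared deviations of the QF samples besides differences between the muscles. The genotype by muscle interaction, which is the test of the title's question, called 7 probe sets, 3 positive and 4 negative. With the replicate numbers as a block within each muscle it called 32, and without Dysf_null_TA 2 or Control_TA 3 it called 4.

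The genotype difference was more negative in TA than in QF for Csrp3 (interaction -3.23 ± 0.34, adjusted p = 0.00142), Ankrd2 (-2.05 ± 0.23, 0.00156), the tubulin Tubb6 (-1.75 ± 0.24, 0.0119) and Cryab (-1.27 ± 0.20, 0.0339; the other Cryab probe set gave 0.32). For Csrp3 the advantage of TA over QF was 4.35 in controls and 1.11 in Dysf_null mice, and for Ankrd2 it was 2.65 and 0.59. The difference was more positive in TA for S100a9 (4.56 ± 0.46, 0.00115) and S100a8 (3.89 ± 0.54, 0.0128). A probe set not named in the gene table gave 3.07 ± 0.29. The calls of S100a8, Tubb6 and Cryab were lost without at least 1 array, with adjusted p-values up to 0.0756, 0.0605 and 0.132, and those of S100a9, Csrp3 and Ankrd2 held without any.

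**Figure D2:**
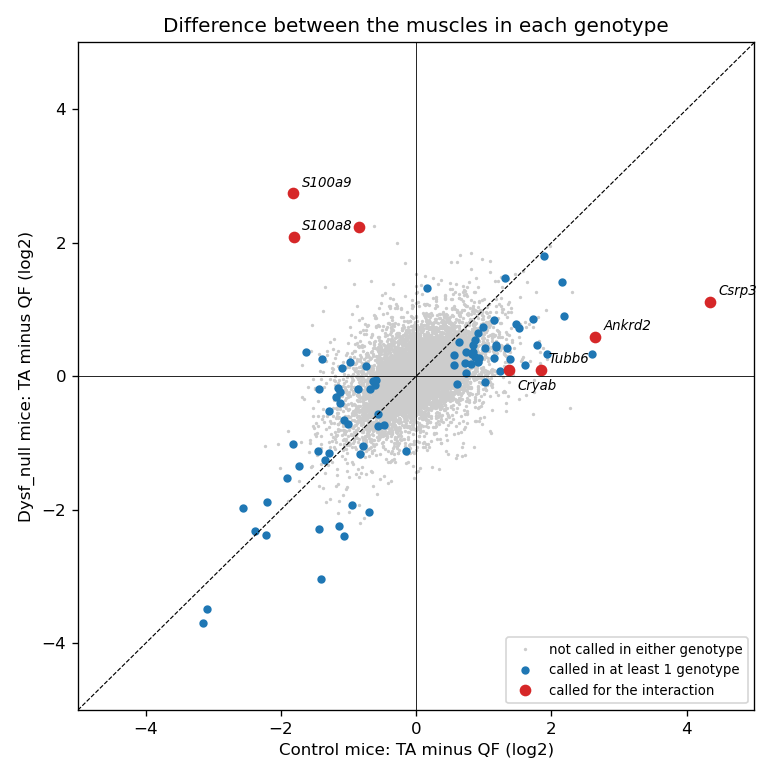
Difference between TA and QF (log2) of each probe set in control mice (horizontal) and in Dysf_null mice (vertical), with the line of equality dashed. Blue points are probe sets called between the muscles in at least 1 genotype, grey points were called in neither, and the 7 called for the interaction (red) lie away from the line, Csrp3 at 4.35 and 1.11 and S100a9 at -1.82 and 2.74.

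Among gene lists, the genotype difference was more positive in TA than in QF for granulocyte markers (adjusted p = 2.23e-07; 2 of 15 genes called, 4 adjusted over the list alone) and blood and erythroid markers (7.93e-05; 0 of 9). It was more negative for slow and oxidative contractile genes (3.89e-07; 2 of 18, 3 adjusted over the list alone), heat shock genes (0.000105; 1 of 23, 3 adjusted over the list alone) and extracellular matrix genes (0.000343; 0 of 29). The list of protein turnover genes was more positive (adjusted p = 0.00326; 0 of 25, 2 adjusted over the list alone), and those of endothelial markers (0.0129; 0 of 20) and of sarcolemma genes (0.0424; 1 of 21) more negative, with adjusted p = 0.136, 0.0853 and 0.099 with an estimated correlation. With the replicate numbers as a block within each muscle the sarcolemma genes had adjusted p = 0.0763, and 3 granulocyte, 1 blood and 1 protein turnover gene were called more positive and 3 contractile and 2 heat shock genes more negative. The fat cell list did not differ (adjusted p = 0.687; 0 of 19, 1 adjusted over the list alone).

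**Figure D3:**
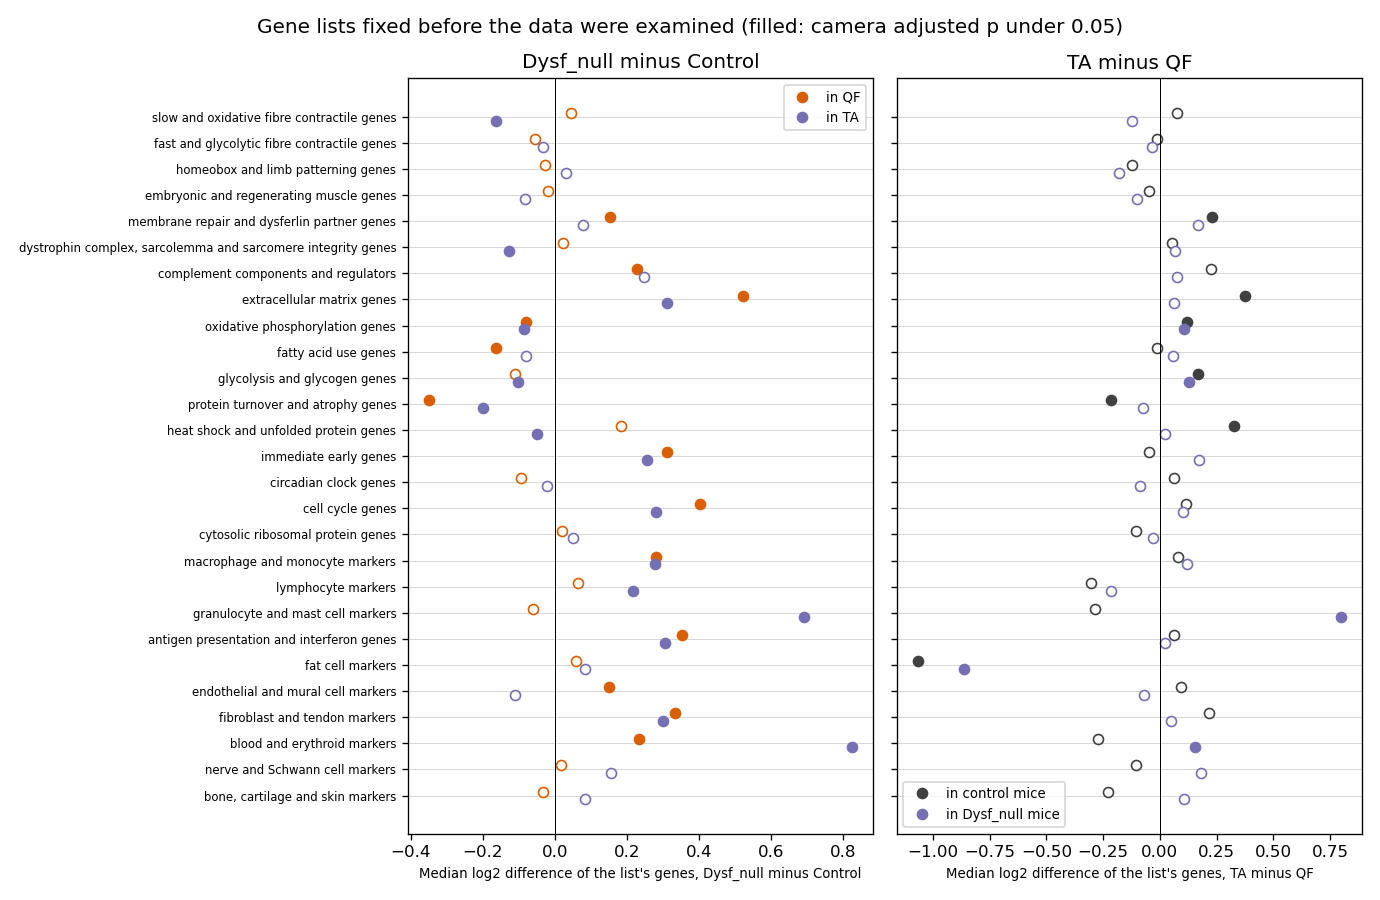
Median log2 difference of the measured genes of 27 gene lists, by genotype in each muscle (left) and between the muscles in each genotype (right). Filled points are lists with a camera adjusted p under 0.05; the fat cell markers stand at -1.07 and -0.86 on the right, and the blood and granulocyte markers at 0.82 and 0.69 for TA on the left.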

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

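The tests of explanations below were chosen after the results were seen, while the splits of the samples had been planned, except the count for the interaction over the splits that part every pair. The genes and lists whose interaction is given passed its test of a genotype difference in TA unlike that in QF, for 3 of the 8 lists only at camera's preset correlation. The antigen presentation genes, weighed for their rise in both muscles, did not (interaction, list adjusted p = 0.687). The groups held 3 arrays each, too few for a test of single outlying arrays.

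The interaction was 4.56 ± 0.46 for S100a9, 3.89 ± 0.54 for S100a8, -3.23 ± 0.34 for Csrp3, -2.05 ± 0.23 for Ankrd2, -1.75 ± 0.24 for Tubb6, -1.27 ± 0.20 for Cryab and 3.07 ± 0.29 for a probe set not named in the gene table. Of lists that passed, the median interaction was 0.44 for granulocyte and mast cell markers, 0.43 for blood and erythroid markers and 0.12 for protein turnover genes. It was -0.23 for slow and oxidative contractile genes, -0.39 for heat shock genes, -0.31 for extracellular matrix genes, -0.24 for endothelial and mural cell markers and -0.14 for dystrophin complex, sarcolemma and sarcomere integrity genes. With an estimated correlation the protein turnover, endothelial and sarcolemma lists did not pass (adjusted p = 0.136, 0.0853 and 0.099), nor did the sarcolemma list with the replicate numbers as a block within each muscle (0.0763). The count of 7 was not separated from chance: 6 of 100 splits of the arrays within muscles gave as many, the real one included here and in the counts below. The highest of the others, 113, had the genotype swapped in 1 muscle, which turns the interaction into the average, and without that split 5 gave as many, with a highest other of 41. Since same-numbered arrays deviated together in QF, and only weakly in TA, the 32 splits that part every such pair were also counted. Of these 3 gave as many, or 2 of 31 without the swap, with a highest other of 7, so the count was not separated from chance there either. All splits used the fit without the replicate numbers. With them as a block within each muscle the interaction called 32, and no splits were run on that fit.

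Granulocyte markers were higher in Dysf_null_TA than in Control_TA, with a list median of 0.69, and Acp5, Mmp9 and Car2, genes also expressed by osteoclasts, rose. These 3 prompted a list of 11 osteoclast genes, whose other 8 did not pass. Of these, Ctsk gave 1.43 ± 0.29 (limma adjusted p = 0.0688), Src 0.39 and Tcirg1 0.33, and 5 lay between -0.10 and 0.07. A single array did not account for the granulocyte shift, since the lowest median without any 1 array was 0.54. Bone or marrow carried over with the TA sample stayed open: osteoblast and osteocyte genes, listed afterwards, had a median of 0.57 (limma's camera adjusted p = 0.0128, and adjusted p = 0.0687 with an estimated correlation). Their differences were positive for 6 of 7, with Dmp1 the highest (1.04 ± 0.35, limma adjusted p = 0.608). On the probe set used for each gene 0 of 7 passed, but that of Ibsp (-0.35) was 1 of 2, and the other passed (2.68, limma adjusted p = 0.0179). Blood and erythroid markers, which marrow or blood in the sample would raise, were higher too (median 0.82, 9 of 9 positive, adjusted p = 5.31e-13). The fixed bone, cartilage and skin list had a median of 0.08 (adjusted p = 0.506). Most of its genes mark cartilage or skin, which carried-over bone or marrow need not raise, and it took Ibsp at -0.35. Its lack of a shift therefore cannot argue against this explanation. The osteoblast values alone met the criterion first written for this explanation, and the condition on the fixed list was added after that outcome was known, so the test is weak evidence either way. An infiltration of neutrophils with genotype remains a further open explanation for TA and was not tested. The rise was not seen in QF, where 7 of 15 granulocyte markers were positive (median -0.06, camera adjusted p = 0.0605). There S100a9 gave -1.82 ± 0.33 (limma adjusted p = 0.028).

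Antigen presentation genes were higher in Dysf_null arrays of both muscles. A strain variant in the H2 region, changing the signal of its own genes, would concern the H2 genes and not Cd74 and B2m, which lie on other chromosomes. For the H2 genes it stayed open, since 5 of 5 had a positive average (median 0.88) on the probe set used for each, and probe sequences were not tested. The probe sets of H2-K1 differed, with averages of 0.80, 0.58 and -0.28. More macrophages in the Dysf_null samples could also not be excluded: their markers were shifted by a median of 0.24 on average over both muscles, against 1.20 for Cd74. An effect of genotype on these genes within the tissue is likewise open and untested.

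Csrp3, Ankrd2 and Cryab, on 1 of its 2 probe sets, were higher on every Control_TA array than on any array of the other 3 groups. For Csrp3 the Dysf_null_TA arrays lay between those of Control_TA and of QF. A mislabelled muscle was argued against by Hoxa11, whose lowest TA array lay at least 1.65 above the QF arrays, all of them at the floor. As the whole cause, fewer slow fibres in Dysf_null_TA were argued against by 9 slow contractile isoforms, listed once the values were known, with a median difference of -0.0224 (SD 0.27) and 0 called, against -1.41 to -2.68 for the 3 genes. The fixed list of 18 slow and oxidative contractile genes, Csrp3 and Ankrd2 included, had a median of -0.16. The interaction of these isoforms was negative for 8 of 9 (median -0.21, limma's camera adjusted p = 0.0304, and adjusted p = 0.177 with an estimated correlation), so a smaller shift of slow fibres between the muscles stayed open. The genotype remains an open explanation. So does a difference in handling or loading of the Control_TA muscles, about which the labels say nothing.

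For the average over both muscles, 1 of 100 splits within muscles, the real one, gave as many as 113 probe sets, and the highest other was 19. Among the 32 splits that part every same-numbered pair, 1 did so too, the real one, with a highest other of 7. By the criterion of a share under 0.05 this count was separated from chance. The splits moved the genotype in each muscle separately, and nothing states that QF and TA came from different mice, so chance was not excluded. The 10 splits of 3 arrays against 3 are too few for a share under 0.05. The real and highest other counts were 42 and 0 for genotype in TA, 76 and 0 for muscle in Control and 31 and 1 for muscle in Dysf_null mice. For genotype in QF they were 47 and 411, and 3 of the 10 splits gave as many. The split with 411 kept the pairs numbered 2 and 3 whole on opposite sides, which points to a structure of the QF samples along their replicate numbers. Of the 4 splits that part every pair, the highest other gave 0, and the count with the replicate numbers as a block within each muscle was 273.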

How the results depend on the processing

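The block within each muscle, array weights and leaving out both QF arrays numbered 2 were chosen after the data were seen, and the other alternatives had been planned. The count for genotype in QF (47) was 7 without the intensity trend, 0 with only its 2 groups (limma, 406 at an unadjusted p under 0.05), 16 without both QF arrays numbered 2, 23 with array weights and 273 with the replicate block within muscle. For genotype in TA (42) it was 159 with that block and 192 with array weights. For muscle in Control (76) it was 42 without the trend and 21 with only its 2 groups, and for muscle in Dysf_null (31) it was 52 with array weights and 9 with only its 2 groups. For the interaction (7) it was 32 with the block within muscle. For the average (113) it was 56 without the trend, 474 with that block and 191 with array weights. The correlation of the muscle differences (0.473) was 0.214 without both QF arrays numbered 2, and that of the genotype differences (0.193) was 0.252 with the stricter filter. Fewer arrays entered the fits of 2 groups and those without the arrays numbered 2. Fewer arrays need not lower a count, since for genotype in TA (42) the fit of only its 2 groups called 51. The causes of these changes were not tested.

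Leaving out 1 array gave 21 to 82 for genotype in QF, 14 to 45 in TA, 37 to 145 for muscle in Control, 20 to 36 in Dysf_null, 4 to 8 for the interaction and 60 to 129 for the average. The correlations ranged from 0.186 to 0.526 and from 0.112 to 0.234. The replicate number as 1 block over both muscles, which the arrays did not bear out, gave 65, 50, 105, 39, 8 and 159 in the order QF, TA, Control, Dysf_null, interaction and average. The block within muscle kept 120 of the 120 named genotype and interaction calls. Of genes taken by the rule that had not passed, 25 of 90 in QF, 19 of 87 in TA, 25 of 76 for the average and 11 of 108 for the interaction passed with it. Of 174 named calls, 88 held without any single array, 86 were lost without at least 1, and 0 changed sign. Without the trend 65 were lost, without both QF arrays numbered 2 it was 43, as deposited 33, and with 1 block over both muscles 2.

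Of 63 list calls, 42 held with an estimated correlation, 58 as deposited, 53 with the mean of a gene's probe sets and 54 without both QF arrays numbered 2, and 49 of 51 held with the block within muscle. The 2 lost with that block were the lymphocyte markers in TA (adjusted p = 0.0599) and the sarcolemma genes for the interaction (0.0763). It added 3: heat shock (up, 0.0120) and glycolysis genes (down, 0.0392) in QF and nerve markers (up, 0.0442) in TA. The protein turnover shift between muscles in Control was among those lost as deposited. As deposited, the median difference of all probe sets between muscles in Control was -0.10, against 0 after normalization. The odds ratio near Dysf (1.52) lay between 1.26 and 1.71 in the other settings. The other settings for the dysferlin transcript were not run, because no probe set carried its name. Values near the floor limit what the arrays show for weakly expressed genes.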

Other observations

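Nothing here was tested for an explanation, and all lists named were fixed before the data were examined. Averaged over both muscles, the co-chaperone Fkbp5 fell by 1.04 ± 0.16 (adjusted p = 0.00475), and the metal-binding proteins Mt1 and Mt2 fell by 1.14 ± 0.20 and 1.26 ± 0.15 (0.0128 and 0.00127). In TA alone Fkbp5, Mt1 and Mt2 did not pass (-0.88, -0.71 and -0.69), although Mt2 did with the replicate numbers as a block within each muscle (adjusted p = 0.039). Granulocyte markers had no list call in QF (adjusted p = 0.0605), where S100a9 fell and 3 of 15 fell adjusted over the list alone and with the replicate block.

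Several lists were called in 0 of the 6 comparisons. In QF and TA by genotype, the camera adjusted p was 0.215 and 0.336 for fast and glycolytic contractile genes, 0.557 and 0.986 for homeobox and limb patterning genes, and 0.64 and 0.426 for embryonic and regenerating muscle genes (with the replicate block 1 of these rose and 1 fell in QF, and 1 fell in TA). It was 0.356 and 0.319 for circadian clock genes, 0.973 and 0.521 for cytosolic ribosomal protein genes, 0.557 and 0.057 for nerve and Schwann cell markers (in TA 0.0442 with the replicate block within each muscle), and 0.437 and 0.506 for bone, cartilage and skin markers. Of 26 homeobox and limb patterning genes, Hoxa11 alone passed between the muscles, in both genotypes, and the list had adjusted p = 0.366 in Control and 0.874 in Dysf_null mice. Averaged over both muscles, complement genes were shifted upward (median 0.23, adjusted p = 0.0118) with 0 of 12 past the threshold, 1 risen adjusted over the list alone and 1 with the replicate block, and fatty acid use genes downward (median -0.15, adjusted p = 0.0194, and adjusted p = 0.129 with an estimated correlation; 1 gene fell with the replicate block).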
